A study of Mus musculus with 4 samples.

How the data were processed

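RNA was measured in 4 mouse libraries: wild-type ES cells (WT_ES), wild-type NPCs (WT_NP), and the same cell types lacking Dnmt3a and Dnmt3b (DKO_ES and DKO_NP), with 1 library per group. Per the labels' protocols, 5 µg of total RNA was depleted of rRNA and made into libraries with the TruSeq kit and 15 cycles of PCR, and single-end reads of 50 cycles were sequenced on a HiSeq2000. Per the submitters' processing notes, Bowtie and TopHat were used with the mouse build mm9; their versions are not given in the sources used here, nor are the program that computed FPKM, its annotation or its treatment of reads that map to several places. The protocol does not state that strand was kept, so overlapping antisense genes cannot be told apart.

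The authors deposited FPKM for 23235 gene symbols in 1 table, with 18 blank rows that were left out. All 4 value columns carry sample titles, and 0 columns were left unmapped. An exact 0 can be a failed estimate, because Lars2, a gene used by every cell, is at 0 in WT_ES and at 10341 FPKM in DKO_ES; a 0 is therefore given as listed at 0, with no fold against it.

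The depth behind the values was read from their steps. Low FPKM values of many genes are whole multiples of what 1 read is worth, and comparing low genes between libraries gave the relative denominators of the libraries: 2.63 in WT_NP, 1.09 in DKO_ES and 1.82 in DKO_NP, relative to 1 in WT_ES. With these, 2031 of 3082 low genes tried (65.9%) came out whole within 0.04 read. Exon lengths from GENCODE release M21 (GRCm38), found for 20846 symbols (89.7%), turned the steps into approximate denominators of 14.5, 38.1, 15.8 and 26.3 M reads in WT_ES, WT_NP, DKO_ES and DKO_NP, and FPKM into approximate reads per gene. Reads so estimated were a median of 1.12 times those from the steps, with 10th and 90th percentiles of 0.977 and 2.62. Summed over genes of 1 kb or more they exceeded the denominator in WT_ES (23.8 M), DKO_ES (25.7 M) and DKO_NP (27.6 M), so the read numbers are rough. No coordinates are given, since the values were made on mm9 and the annotation used here is of GRCm38; chromosomes come from that annotation.

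For each comparison the log2 ratio was log2((FPKM + 1)/(FPKM + 1)), with a pseudocount of 1 FPKM, for genes at or above 1 FPKM in at least 1 library of the pair, and genes were counted at a log2 ratio of 1 (2-fold) or more in size. This scale understates differences of low genes. The comparisons were WT_NP with WT_ES, DKO_NP with DKO_ES, DKO_ES with WT_ES and DKO_NP with WT_NP, and the difference of the 2 differentiation ratios, DKO minus WT. No test was run: each comparison sets 1 library against 1, and an additive model of genotype and cell type over the 4 libraries, which leaves 1 residual degree of freedom, was not used here. Median scaling divided each library by the median of its ratios to the 4-library geometric mean over genes at or above 1 FPKM in all libraries; the factors were 1.32, 0.671, 1.25 and 0.908 for WT_ES, WT_NP, DKO_ES and DKO_NP. Folds of single genes are ratios of median-scaled FPKM without a pseudocount, and their 95% intervals are exact (Clopper-Pearson) intervals of the approximate reads, which cover counting error only: PCR copies are not independent molecules. Where the approximate reads of a gene are too many, its interval is too narrow. A value of 3 reads in a gene of 2 kb corresponds to 0.103, 0.0393, 0.0951 and 0.0569 FPKM in WT_ES, WT_NP, DKO_ES and DKO_NP. In data simulated with counting noise alone, 1, 3, 0 and 0 unchanged genes passed 2-fold in the 4 comparisons in the order above (of 12157, 11925, 11454 and 12149), and of genes set to a 2.5-fold difference 71%, 78%, 75% and 74% passed.

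Before the data were examined, 26 gene lists were fixed: core, naive, and formative and primed pluripotency; neural progenitor; postmitotic neuron; retinoic acid response; anterior and posterior Hox; mesoderm; endoderm and visceral endoderm; trophoblast; neural crest; glia; fibroblast as feeder cell; germline; cleavage-stage embryo; imprinted genes; DNA methylation machinery; Polycomb and Trithorax; glycolysis and hypoxia; p53 targets; cell cycle; housekeeping; ribosomal proteins; replication-dependent histones; and clustered protocadherins. Of their members 5 were found under another symbol and 3 were not found. Each list was described by the median log2 ratio of its members at or above 1 FPKM, the number at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of equal size matched on mean expression in 20 bins. Lists with fewer than 3 such members have no median. Lists of interferon-induced and erythroid genes were added after the data were seen.

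Genes were named by a rule fixed before the data were examined: Dnmt3a and Dnmt3b; in each comparison the 8 highest and 8 lowest log2 ratios among genes at or above 5 FPKM in either library, leaving out small RNAs and unnamed models; the 6 highest and 6 lowest differences of ratios; and up to 4 members of each list with the ratio largest in size. Some single genes that this rule selects are not reported here. A few other list members, Rn45s and Isg15 were named after their values were seen. The highest and lowest genes also include Nanogpd, a copy of Nanog, and AF357425, AF357426 and AF357355, which are short RNA entries; AF357425 stood at 1898 FPKM in WT_ES and was listed at 0 in DKO_ES.

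Pearson and Spearman coefficients across genes are of deposited values and are descriptions only. The alternatives fixed before the data were examined were a pseudocount of 0.1 FPKM, no filter, a filter of 5 FPKM, median scaling, scaling by the upper quartile and a threshold of 4-fold. The comparison of genes with a CpG island inside the gene body was not run, because it needs the genome sequence, which was not used here; islands within transcripts were searched instead, as an alternative chosen after seeing the data. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.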

Results

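Messenger and other long RNA was measured by sequencing of rRNA-depleted total RNA from 4 mouse cell cultures, 1 library each. Embryonic stem (ES) cells, which can form all tissues of the embryo, were grown with serum and leukemia inhibitory factor and taken at day 0. They were either wild type (WT_ES), of the J1 background and strain 129S4/SvJae, or double knockout for Dnmt3a and Dnmt3b (DKO_ES), the genes of the enzymes that place new methyl groups on DNA. Neural progenitor cells (NPCs) were made from each line by 4 days as embryoid bodies, which are floating clusters of differentiating cells, and 2 days of retinoic acid, and were taken at day 6 (WT_NP and DKO_NP). The series concerns CpG islands inside genes in these cell types. The deposited values were FPKM for 23235 gene symbols; 13125 genes reached 1 FPKM in WT_ES, 12756 in WT_NP, 13128 in DKO_ES and 12878 in DKO_NP. The reads assigned to genes of at least 1 kb were estimated to be 1.23 times as many in WT_NP as in WT_ES, 1.08 times in DKO_ES and 1.16 times in DKO_NP. No difference given here has a replicate check, since each group holds 1 library, and the 95% intervals beside folds cover counting error only, from approximate read numbers. Folds are between libraries after median scaling unless stated.

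The targeted genes were lower in both knockout libraries. Dnmt3a stood at 35.3 FPKM in WT_ES and 12.3 in DKO_ES, and at 17.2 in WT_NP and 4.14 in DKO_NP. Dnmt3b stood at 140.3 FPKM in WT_ES, 13.9 in DKO_ES, 9.98 in WT_NP and 5.22 in DKO_NP. Between ES cell libraries Dnmt3a was 2.72-fold lower in the knockout (interval 2.58 to 2.87) and Dnmt3b 9.56-fold lower (8.94 to 10.2), while between NPC libraries they were 5.64-fold (5.28 to 6.02) and 2.59-fold (2.35 to 2.85) lower. RNA of both genes remained in the knockouts, and values per gene cannot show which exons it came from. The maintenance methyltransferase gene Dnmt1 stood at 140.2 FPKM in WT_ES and 132 in DKO_ES. Dnmt3l, which encodes a cofactor of the 2 missing enzymes, stood at 148 FPKM in WT_ES and 250.2 in DKO_ES, and at 1.73 in WT_NP against 12.4 in DKO_NP, 5.26-fold higher (4.48 to 6.24).

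Differentiation of wild-type cells, WT_NP against WT_ES, replaced pluripotency transcripts by those of retinoic acid response, Hox, neural and mesendodermal genes. Tdgf1, a co-receptor for the growth factor Nodal, was 409-fold lower in WT_NP (330.2 to 510.3), Pou5f1, the central pluripotency factor, was 50.1-fold lower (46.0 to 54.4) and Zfp42, a marker of naive ES cells, was 72.3-fold lower (64.6 to 81.1). Cyp26a1 and Cyp26b1, whose enzymes degrade retinoic acid, were 451-fold (247 to 838) and 535-fold (353 to 852) higher. Embryonic globin genes Hbb-bh1, Hba-x and Hbb-y, made by primitive red blood cells, were listed at 0 in WT_ES and at 328, 242 and 193 FPKM in WT_NP. Of 14086 genes at or above 1 FPKM in either library, 901 were at least 2-fold higher and 5876 at least 2-fold lower as deposited. The median gene was lower by a log2 ratio of -0.82, and after median scaling the counts were 2287 higher and 1592 lower, so that the higher share of these moved from 13.3% to 59.0%. Values from here on in this comparison are relative to that shift.

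Pluripotency genes were lower together. Among 12 core pluripotency genes the median log2 ratio was -3.89 and 11 were at least 2-fold lower; Utf1 was 72.1-fold lower (57.7 to 91.5) and Dppa5a 36.4-fold lower (34.5 to 38.5). All 14 naive pluripotency genes were at least 2-fold lower, with a median of -3.72, among them Fgf4, a growth factor gene of ES cells, at 200.5-fold (146 to 276), Esrrb at 65.5-fold (58.4 to 74.0) and Nr0b1 at 144-fold (83.5 to 258). Tdh, the threonine dehydrogenase on which mouse ES cells depend, was 72.7-fold lower (62.4 to 85.7). Of 9 genes of formative and primed pluripotency, 6 were at least 2-fold lower and 1 higher, with a median of -1.95; Otx2 was 18.1-fold lower (14.6 to 22.4). Of 21 germline genes, 17 were at least 2-fold lower (median -2.63), for example Mael, a piRNA pathway gene, at 30.3-fold (22.0 to 41.9). Genes of the cleavage-stage embryo had a median of -1.10, with 4 of 8 at least 2-fold lower; Zscan4c was 8.07-fold lower (6.12 to 10.7), though reads of the near-identical Zscan4 copies cannot be told apart with certainty.

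Developmental genes were higher in WT_NP. The 12 retinoic acid response genes had a median log2 ratio of 5.01, and 11 were at least 2-fold higher, including the receptor gene Rarb at 267-fold (160.3 to 516) and the homeobox gene Meis1 at 159.5-fold (127 to 204). Of 15 anterior Hox genes, which pattern the hindbrain and neck, 14 were at least 2-fold higher (median 4.39). Of 18 neural progenitor genes 14 were higher and 1 lower (median 1.66), with the homeobox genes Meis2 219-fold (139 to 372) and Irx3 40.8-fold (28.2 to 62.8) higher. Of 15 genes of endoderm and visceral endoderm 14 were higher (median 2.94), among them Apoa1, an apolipoprotein of the yolk sac and liver, at 107-fold (56.6 to 218) and the transcription factor Gata4 at 35.2-fold (28.5 to 43.7). Of 13 mesoderm genes 10 were higher (median 2.03), with Kdr, the receptor of blood vessel precursors, at 84.3-fold (58.0 to 129) and Pdgfra at 43.5-fold (34.7 to 54.9). Markers of other cell types also stood higher, with 7 of 10 trophoblast genes higher and 3 lower (median 1.36). Of 7 neural crest genes 5 were higher (median 1.63, but -1.18 as deposited with a filter at 5 FPKM). Of 4 posterior Hox genes 3 were higher, but their median of 1.35 lay inside the range of random lists. Fibroblast genes had a median of 0.72, with 6 of 12 higher and 2 lower, and 4 glial genes a median of 0.35. Both medians lay inside the range of random lists, and as deposited both were below 0, at -0.16 and -0.39. Postmitotic neuron genes did not move one way, with 4 of 15 higher, 6 lower and a median of -0.24; the neuronal tubulin gene Tubb3 was 5.94-fold lower (5.31 to 6.69). Imprinted genes had a median of 1.74 with 19 of 28 higher, among them Igf2, a fetal growth factor, at 38.1-fold (35.5 to 41.0), and clustered protocadherins, adhesion genes of neurons, one of 1.30 with 16 of 24 higher. Cell cycle genes had a median of -0.80, below the range of random lists. The medians of p53 targets (-0.58), the DNA methylation machinery (-0.52), histones (-0.41), housekeeping genes (-0.40) and ribosomal proteins (-0.40) were below 0 but inside that range.

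Differentiation of knockout cells, DKO_NP against DKO_ES, went in the same direction for most of these groups. Cyp26a1 stood at 0.222 FPKM in DKO_ES and 226 in DKO_NP, the anterior Hox genes Hoxd4 and Hoxb2 were 637-fold (249 to 2346) and 518-fold (186 to 2647.5) higher, and Crabp2, a retinoic acid carrier, was 43.7-fold higher (39.2 to 48.8). Stra8, a retinoic acid target of germ cells, was 49.5-fold higher (44.0 to 55.9), at 9.81 FPKM in DKO_ES and 352 in DKO_NP. Tdgf1 was 262-fold lower (216 to 318), Pou5f1 35.8-fold lower (33.4 to 38.4) and Trh, the thyrotropin-releasing hormone gene, 83.1-fold lower (71.7 to 96.8). Of 14050 genes, 1102 were at least 2-fold higher and 3067 lower as deposited, with a median log2 ratio of -0.43 over all genes. After median scaling, 1656 were higher and 1570 lower, and the higher share moved from 26.4% to 51.3%.

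Relative to that shift, 10 of 12 core pluripotency genes were at least 2-fold lower (median log2 ratio -2.92), as were all 14 naive pluripotency genes (median -2.65). Of 13 retinoic acid response genes 12 were higher and 1 lower (median 4.79), and of 15 anterior Hox genes 14 were higher (median 4.63). Neural progenitor genes had a median of 2.64 with 21 of 22 higher and 1 lower; Zic1, a factor of the dorsal neural tube, stood at 0.0372 FPKM in DKO_ES and 17.96 in DKO_NP, and Hes5, a target of Notch signalling in neural stem cells, was 30.4-fold higher (20.96 to 44.8). Postmitotic neuron genes had a median of 0.62, with 7 of 20 higher and 2 lower. Of 13 endoderm genes 11 were higher and 1 lower (median 1.68), and of 10 mesoderm genes 6 were higher (median 1.03), with Cdh5, a cadherin of blood vessels, at 67.2-fold (31.5 to 164). Of 6 posterior Hox genes 3 were higher (median 1.80); Hoxb6 was listed at 0 in DKO_ES and at 33.7 FPKM in DKO_NP. Germline genes had a median of -0.87, with 9 of 23 lower and 1, Dazl, higher; Dazl, an RNA-binding protein gene of germ cells, was 3.49-fold higher (3.26 to 3.73). Replication-dependent histone genes, whose transcripts carry no poly(A) tail, had a median of 0.83 with 22 of 59 higher; Hist1h1e was 4.46-fold higher (4.30 to 4.63). Rpl26, a ribosomal protein gene with near-identical pseudogene copies, stood at 1465 FPKM in DKO_ES and 0.508 in DKO_NP, while the median over 77 ribosomal protein genes was -0.47; its value is uncertain, and the cause was not tested.

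**Figure D1:**
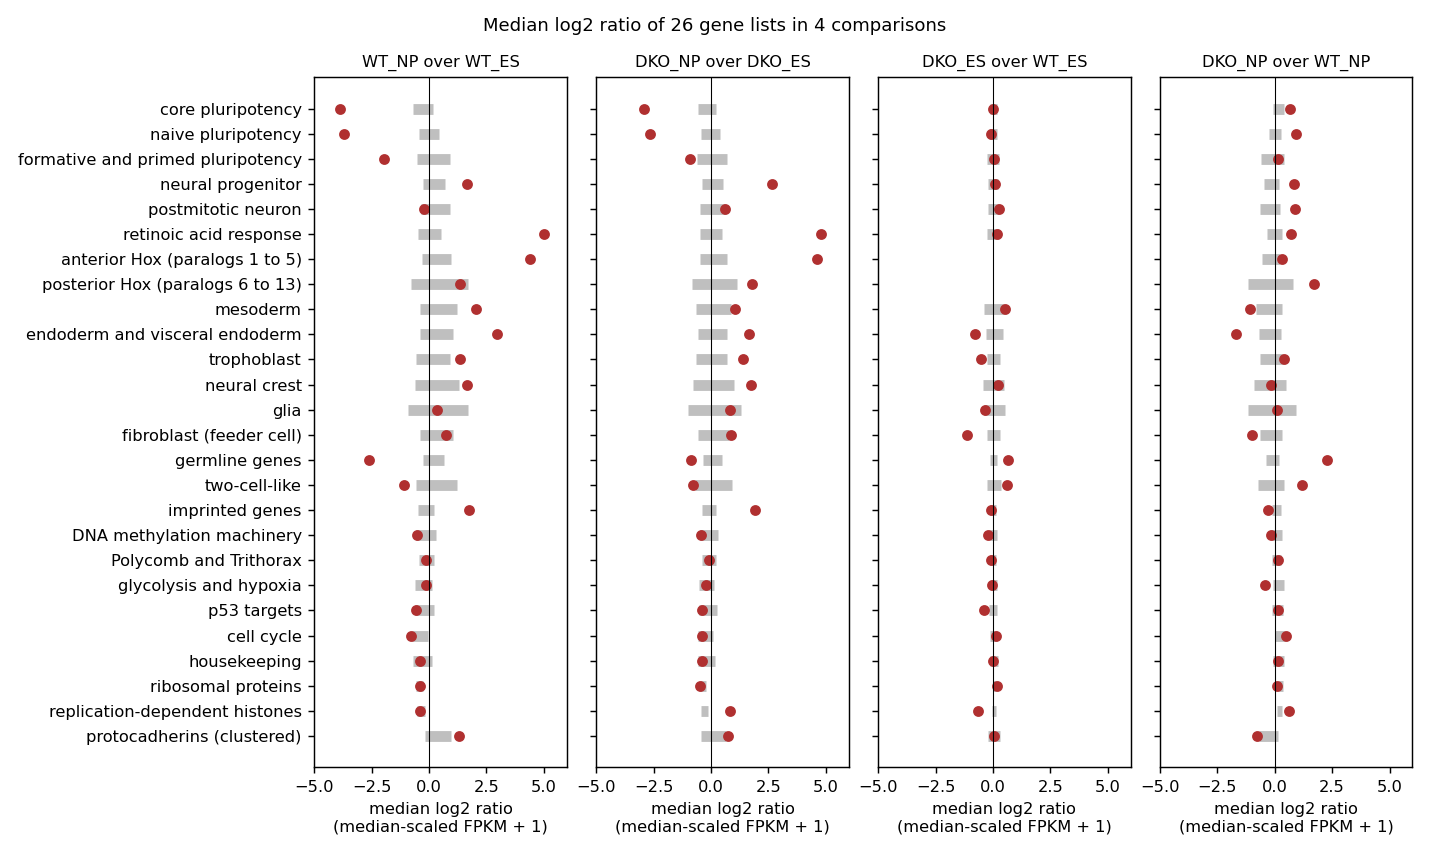
Median log2 ratio of each of 26 gene lists (red points) in the 4 comparisons, from median-scaled FPKM plus 1; grey bars span the central 95% of medians of 10000 random lists matched on expression. Core and naive pluripotency lists sit far to the left and retinoic acid response and anterior Hox lists far to the right in both differentiation panels, and the germline list stands at 2.27 in DKO_NP over WT_NP. The Hox lists have no point in DKO_ES over WT_ES because only 2 members each reached 1 FPKM.

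Before differentiation, DKO_ES against WT_ES, the knockout differed at few genes, and many of the highest genes were X-linked. Cox7b2, a subunit gene of mitochondrial cytochrome c oxidase on chromosome 5, was 55.9-fold higher (23.8 to 228). Usp26, an X-linked deubiquitinase gene of the testis, was 21.2-fold higher in DKO_ES (18.7 to 24.1), and Xlr3c, Rhox1 and Efhc2, all on chromosome X, were 28.3-fold (16.4 to 51.3), 23.8-fold (12.5 to 58.8) and 14.5-fold (12.2 to 17.4) higher. Magea4 and Rhox2b, also on chromosome X, were listed at 0 in WT_ES and at 10.7 and 10.3 FPKM in DKO_ES. The RNAs without protein product that lie in 1 imprinted cluster on chromosome 12 were lower, namely Meg3 by 15.6-fold (14.9 to 16.4), Rian by 18.5-fold (17.7 to 19.3) and Mirg by 20.8-fold (16.8 to 26.4). Of 13596 genes, 356 were at least 2-fold higher and 207 lower as deposited, and 348 and 156 after median scaling, with a median log2 ratio of -0.06 over all genes. Rhox and Xlr genes have close copies, so the reads of single members are uncertain.

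List medians, counts and percentiles in this paragraph are as deposited unless stated, while folds of single genes are after scaling. Of 25 germline genes 9 were at least 2-fold higher in DKO_ES and 1 lower. The list's median log2 ratio of 0.62 lay at percentile 100 among matched random lists. After scaling 10 germline genes were higher (median 0.65). Asz1, a piRNA pathway gene, was 26.3-fold higher (11.5 to 86.0) and Hormad1, a gene of meiotic chromosome pairing, 4.02-fold (3.61 to 4.48). Genes of the cleavage-stage embryo had a median of 0.58 with 1 of 8 at least 2-fold higher. Core and naive pluripotency genes had medians of -0.06 and -0.17, the first of which was 0.02 after scaling. Within them Dppa3, a germ cell and egg factor, was 3.93-fold higher (3.44 to 4.51) and the naive-state factors Klf4 and Tbx3 were 2.64-fold (2.49 to 2.80) and 3.16-fold (2.87 to 3.49) lower. Formative and primed genes had a median of -0.03, which was 0.04 after scaling, and Lef1, a partner of beta-catenin, was 4.46-fold lower (3.43 to 5.94). Fibroblast genes, read as markers of feeder cells, had a median of -1.28, at percentile 0 of the random lists. Of 10, 6 were at least 2-fold lower, against 5 after scaling (median -1.13). Col1a1 was 7.94-fold (6.43 to 9.87) and Tagln 4.19-fold (3.63 to 4.86) lower. The cells were grown on feeders in earlier passages, and the fibroblast list stood lower in the knockout libraries on both days. On day 6 the list need not mark feeders, since Col3a1 was 37.5-fold higher in WT_NP than in WT_ES (30.5 to 46.7). Col1a2 went the other way from the list on day 6, at 6.23 FPKM in WT_NP and 11.7 in DKO_NP. Endoderm genes had a median of -0.91 with 1 of 6 lower, and trophoblast genes one of -0.60 with 1 of 6 lower. Mesoderm genes had one of 0.49, or -0.11 with no filter. None of 5 mesoderm genes was at 2-fold, against 1 higher after scaling (median 0.53). Histone genes had a median of -0.74 with 15 of 60 lower, against 13 lower after scaling (median -0.67). Hist1h3e was 4.05-fold lower (3.86 to 4.25). Targets of the tumour suppressor p53 had a median of -0.47 with 1 of 13 at least 2-fold lower as deposited, the growth regulator Phlda3, which was 1.98-fold lower after scaling (1.80 to 2.17).

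After differentiation, DKO_NP against WT_NP, germline and neural genes were higher and endoderm and mesoderm genes lower in the knockout. Dazl was 56.1-fold higher (45.4 to 70.6), at 0.733 FPKM in WT_NP and 55.7 in DKO_NP, and Sohlh2, a transcription factor gene of early germ cells, was 34.4-fold higher (28.2 to 42.0). Hes5 was 8.80-fold higher (7.34 to 10.6). Gata4, a factor of endoderm and heart, stood at 30.4 FPKM in WT_NP and 0.779 in DKO_NP, 52.8-fold lower (41.9 to 67.04), and Hbb-bh1 was 32.0-fold lower (28.0 to 36.7). Meg3 and Rian were 211-fold (194 to 231) and 92.2-fold (86.6 to 98.3) lower. Of 13601 genes, 1382 were at least 2-fold higher and 531 lower as deposited. The median gene was higher by a log2 ratio of 0.39, and after median scaling 648 were higher and 1087 lower, so that the higher share of these moved from 72.2% to 37.3%; list values in this comparison are relative to that shift.

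Germline genes had a median log2 ratio of 2.27, with 21 of 23 at least 2-fold higher and none lower. Tuba3a, a testis tubulin, was 34.3-fold higher (24.1 to 50.4), Tex19.1, a guard against transposable elements, 14.8-fold (12.6 to 17.4) and Rpl10l, a ribosomal protein gene of the testis, 15.0-fold (11.1 to 21.4); Tuba3a and Tuba3b are close copies, so the reads of each are uncertain. The homeobox genes Rhox6 and Rhox9 on chromosome X were 26.6-fold (21.4 to 33.8) and 20.6-fold (17.6 to 24.2) higher. Genes of the cleavage-stage embryo had a median of 1.20 with 5 of 8 higher. Some pluripotency genes also stood higher: 4 of 12 core genes (median 0.68), with Sox2 at 3.42-fold (3.18 to 3.68), and 5 of 14 naive genes with 1 lower (median 0.92), with Zfp42 at 5.49-fold (4.85 to 6.21) and Tbx3 5.44-fold lower (4.55 to 6.57). Pou5f1 stood at 11.04 FPKM in WT_NP and 23.4 in DKO_NP. Formative and primed genes had a median of 0.13 with 1 of 7 higher.

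Neural progenitor genes had a median of 0.82, with 10 of 22 at least 2-fold higher and none lower. Fabp7, a lipid-binding protein of radial glia, was 11.8-fold higher (8.56 to 17.0), Neurog1, a proneural factor, 6.33-fold (4.92 to 8.31) and Sox3 4.40-fold (3.86 to 5.05). Of 20 postmitotic neuron genes 9 were higher and 3 lower (median 0.87), with Tubb3 at 4.35-fold (3.88 to 4.90). Of 14 endoderm genes 11 were at least 2-fold lower and none higher (median -1.70), with Gata6 at 12.9-fold (11.2 to 14.9) and Ttr, a yolk sac and liver carrier protein, at 8.75-fold (6.92 to 11.1). Of 12 mesoderm genes 7 were lower and none higher (median -1.07), with Pdgfra at 13.4-fold (11.9 to 15.0) and Foxc2 at 8.25-fold (6.51 to 10.5). Foxf1a, a factor of lateral mesoderm, stood at 28.0 FPKM in WT_NP and 0.530 in DKO_NP. Fibroblast genes had a median of -0.98 with 5 of 10 lower, among them the collagen gene Col3a1 at 12.9-fold (11.5 to 14.5).

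Retinoic acid response genes went both ways. Of 13, 3 were at least 2-fold higher and 2 at least 2-fold lower (median 0.71), against 7 and 0 as deposited (median 1.14): Stra8 was 9.03-fold higher (8.62 to 9.47), whereas Cyp26b1 was 2.62-fold lower (2.55 to 2.71) and Dhrs3, a retinaldehyde reductase, 2.15-fold lower (2.07 to 2.25). Of 15 anterior Hox genes 3 were higher and 1 lower (median 0.32), and of 5 posterior ones 3 were higher (median 1.72), with Hoxb6 at 8.15-fold (7.11 to 9.41) and Hoxb8 at 7.65-fold (6.39 to 9.29). Trophoblast genes were also mixed, with 4 of 12 higher and 3 lower (median 0.38), among them the placental gene Plac1 at 9.30-fold higher (7.15 to 12.5). Of 29 imprinted genes 4 were higher and 10 lower, with a median of -0.31 that was 0.02 as deposited; Phlda2, a brake on placental growth, was 11.5-fold higher (9.65 to 13.8) and H19, a maternally expressed RNA, stood at 233 FPKM in WT_NP and 927 in DKO_NP. Neural crest genes had a median of -0.17, which was 0.21 as deposited, and 3 glial genes one of 0.11. Cell cycle genes had a median of 0.47 with 2 of 14 higher, among them Ccnd1 at 4.48-fold (4.16 to 4.83). Histone genes had a median of 0.63 with 4 of 59 higher, against 32 as deposited (median 1.05). The 24 clustered protocadherins had a median of -0.78 with 6 lower, against -0.45 with none lower as deposited, or 0.0189 as deposited with no filter, and 17 genes of glycolysis and hypoxia one of -0.43, which was 0.01 as deposited. The DNA methylation machinery stood at -0.17 over 17 genes and at 0.21 as deposited. Polycomb and Trithorax genes (0.16 over 24), p53 targets (0.15 over 13), housekeeping genes (0.15 over 12) and ribosomal proteins (0.10 over 76) had medians nearer to 0. The ribosomal median lay below the range of matched random lists, 0.15 to 0.34, and the others lay inside theirs.

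**Figure D2:**
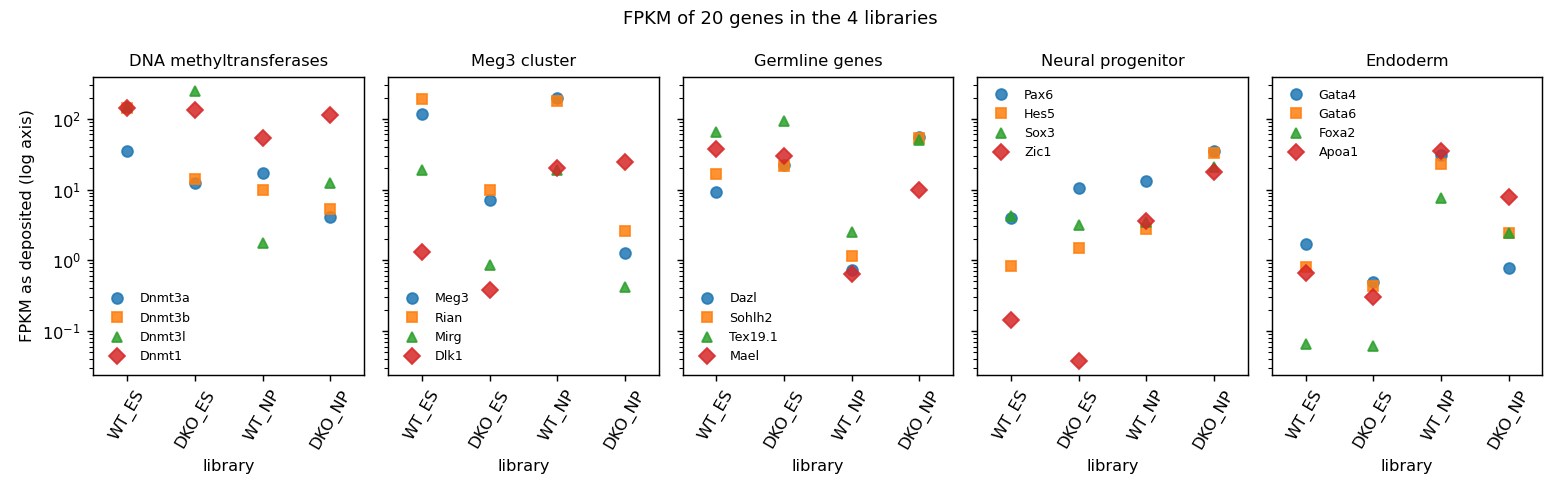
FPKM as deposited (log axis) of 20 genes in the 4 libraries, 1 point per gene and library, grouped by panel into DNA methyltransferases, the Meg3 cluster, germline, neural progenitor and endoderm genes. Dazl is lowest in WT_NP at 0.733 and highest in DKO_NP at 55.7, and Meg3 stands at 7.16 and 1.27 in the knockout libraries against 118 and 199 in the wild type.

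Whether differentiation took the same course in both genotypes was described by the difference of the log2 ratios, DKO minus WT. Across 14713 genes the 2 ratios as deposited had a Pearson r of 0.66 and a Spearman rho of 0.74; genes are not independent replicates. Of 13423 genes in both comparisons, 1071 were at least 2-fold higher in both genotypes and 920 lower in both after scaling, where lists that shared genes only by chance would give 214 and 174. Genes at least 2-fold higher in 1 genotype and lower in the other numbered 40 (higher in WT) and 13 (higher in DKO). As deposited, the difference was at or above 1 for 1735 genes and at or below -1 for 709, with a median of 0.43, and after scaling the counts were 634 and 1296, so that the share of positive ones moved from 70.99% to 32.8%.

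Dazl, Sohlh2, Phlda2 and Rhox9 were among the genes with the highest scaled differences, at 3.68, 4.04, 3.39 and 3.48. Ifi27l1, an interferon-induced gene, had 3.92. Among the lowest was Sfrp5, a secreted Wnt inhibitor, at -4.26; Hbb-bh1 and Foxf1a were also among them but were listed at 0 in WT_ES. Germline genes had a scaled median difference of 1.22 and neural progenitor genes one of 0.73, while mesoderm and endoderm genes had -1.38 and -1.17. Histone genes had the highest list median, 1.31, with 44 of 60 at or above 1. Rpl26 had -9.81, which is uncertain, and Lars2, a mitochondrial tRNA synthetase gene used by every cell, was listed at 0 in WT_ES and at 10341 FPKM in DKO_ES.

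The genotype difference was then compared between cell types. Of 12484 genes, 124 were at least 2-fold higher in the knockout in ES cells and in NPCs and 48 lower in both after scaling, against 10.7 and 7.77 for lists that overlap by chance. These comparisons share no library, but they share the cell lines, since the NPCs were made from the same ES cell lines. A difference between the lines apart from Dnmt3a and Dnmt3b would recur on both days. It cannot be told apart from the genotype here. Across 14713 genes the 2 differences as deposited had a Pearson r of 0.22 and a Spearman rho of 0.20. Dazl was higher and Meg3, Rian and Mirg were lower in the knockout on both days.

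**Figure D3:**
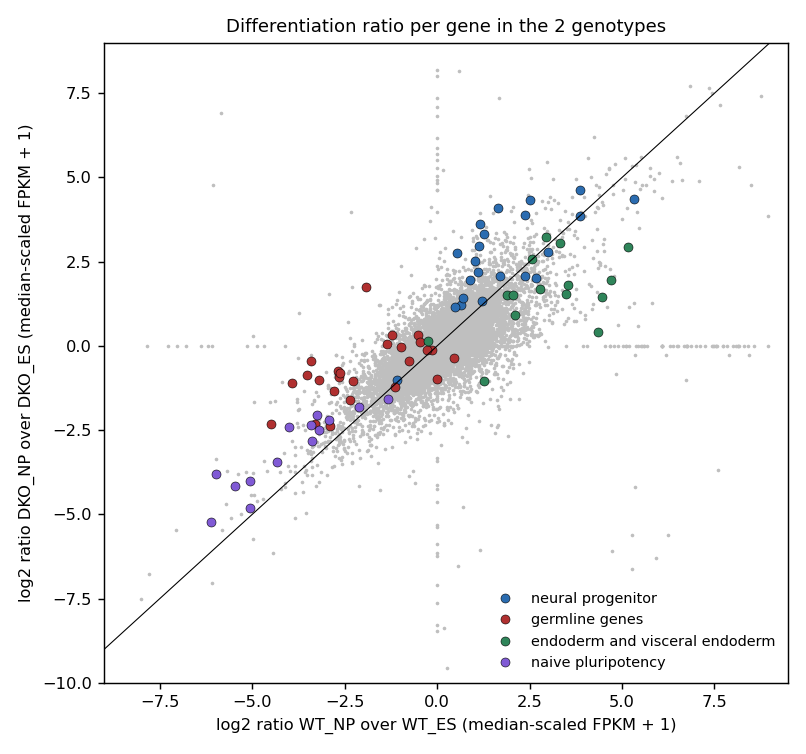
Scaled log2 ratio of NPC over ES cell for each of 14713 genes, wild type on the horizontal and knockout on the vertical axis; the line marks equal ratios, coloured points are members of 4 gene lists, and 6 genes lie outside the axes. Most germline points lie above the line and most endoderm points below it, with list medians of the difference at 1.22 and -1.17.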

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

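The tests of leftover ES cells, of scaling and of slower differentiation were chosen only after the result was seen; the number of cultures was known before. Each result here stood out because the same contrast went opposite ways in 2 settings that hold 1 library per arm, and the difference between the settings was not tested. Values are log2 ratios after median scaling.

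Dazl was lower in WT_NP than in WT_ES, at -1.93, and higher in DKO_NP than in DKO_ES, at 1.74. Sohlh2 did the same, at -2.31 and 1.74. Both are germ cell genes, and the germline list as a whole stood at 2.27 in DKO_NP over WT_NP, so scaling between the 2 libraries does not account for it, since that value is already scaled. Leftover ES cells in the DKO_NP culture are argued against by the median germline gene, which lay at 53.7% of its DKO_ES level, 141 times the 0.382% of Tdgf1, an abundant ES cell transcript that unchanged ES cells would bring along. Tdgf1 was the lowest of 26 pluripotency genes, which had a median of 12.2% and reached 53.8%, within the germline range of 16.1% to 349%. Cells that had left the ES state only in part are therefore not excluded. Lower silencing of germline promoters without Dnmt3a and Dnmt3b, which textbooks describe as methylated genes, may be the reason; this was not tested, as methylation was not analysed here, and a difference between the cultures stays open. Methylation of these promoters in the same cells would test it.

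Mesoderm genes had a median of 0.53 in DKO_ES over WT_ES and -1.07 in DKO_NP over WT_NP. The first rests on 5 genes; as deposited it was 0.49, and -0.11 with no filter, so as deposited its sign depends on the filter. In the NPC libraries the neural list lay above the mesoderm and endoderm lists by at least 1.89, which 1 scaling factor cannot produce. Slower differentiation of the knockout was checked on 14 neural progenitor genes that were at least 2-fold higher in WT_NP than in WT_ES. Their median in DKO_NP over WT_NP was 0.82, and 11 of them were higher in the knockout. This goes against a slower rise of these neural genes. They are members of the list whose difference was to be explained, so they are no separate evidence on the knockout as a whole. Slower loss of pluripotency alone is not excluded, as the core and naive pluripotency lists stood at 0.68 and 0.92 in DKO_NP over WT_NP, both at percentile 100 of random lists. A different mix of lineages in the 1 culture sequenced per genotype may account for it and cannot be told apart from an effect of the genotype, since no second culture was measured.

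Trophoblast genes had a median of -0.52 in DKO_ES over WT_ES and 0.38 in DKO_NP over WT_NP. Replication-dependent histone genes had a median of -0.41 in WT_NP over WT_ES and 0.83 in DKO_NP over DKO_ES, and of -0.67 in DKO_ES over WT_ES and 0.63 in DKO_NP over WT_NP. Hist1h2ak, one of them, stood at -1.03 in the wild type and 1.60 in the knockout on differentiation. Lars2 was listed at 0 in WT_ES alone, which can be a failed estimate. The size of its values of 12.42 and 13.01 against WT_ES is set by the pseudocount, and they are not read as a change of direction. Without WT_ES it stood at -2.50 in DKO_NP over DKO_ES and -1.91 in DKO_NP over WT_NP. The FPKM behind these, 1325 in DKO_NP, 3681 in WT_NP and 10341 in DKO_ES, are uncertain as well, and the cause was not tested.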

How the results depend on the processing

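Genes of 1 kb or more and zeros set to 3 reads were alternatives chosen after seeing the data. Where a value moved, the cause was not tested except for the threshold and the filters, which by construction count other genes. Within a comparison no paired analysis was possible because each group holds 1 library; blocking the genotype difference by cell type over the 4 libraries was not run. Counts follow the order WT_NP over WT_ES, DKO_NP over DKO_ES, DKO_ES over WT_ES, DKO_NP over WT_NP and difference of ratios.

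With median scaling, leaving out DKO_ES over WT_ES, the genes higher were 2287, 1656, 648 and 634, and the genes lower 1592, 1570, 1087 and 1296. With upper-quartile scaling they were 2467, 1749, 628 and 617 higher, and 1408, 1440, 1152 and 1334 lower. At 4-fold, 314, 331, 102, 193 and 204 were higher and 1162, 630, 61, 148 and 169 lower. With a pseudocount of 0.1, DKO_ES over WT_ES had 586 higher and 401 lower, DKO_NP over WT_NP 949 lower, and the difference 2695 higher and 1163 lower. With the filter at 5 FPKM, 539 were higher in WT_NP over WT_ES, 699 higher in DKO_NP over DKO_ES and 454 lower in the difference. Genes of 1 kb or more gave 207 higher and 119 lower in DKO_ES over WT_ES, 287 lower in DKO_NP over WT_NP, and 386 lower in the difference. With no filter all 10 counts stayed within 1.5 times, but those of the 4 comparisons could not change. A gene below 1 FPKM in both libraries cannot reach 2-fold with a pseudocount of 1. The difference of ratios had 1742 higher and 719 lower.

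Dnmt3a had -1.36 in DKO_ES over WT_ES and -2.26 in DKO_NP over WT_NP with median scaling, and -2.03 in the latter with a pseudocount of 0.1; Dnmt3b had -1.23 in DKO_NP over WT_NP with median scaling. All kept their direction.

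Among list medians outside the central 95% of random lists, these changed sign. With no filter, mesoderm in DKO_ES over WT_ES was -0.11, and protocadherins were 0.0189 in DKO_NP over WT_NP and 0.0220 in the difference. Neural crest in WT_NP over WT_ES was -1.18 with the filter at 5 FPKM. With median and upper-quartile scaling, imprinted genes in DKO_NP over WT_NP were -0.31 and -0.35, and in the difference -0.20 and -0.22; the DNA methylation machinery in DKO_NP over WT_NP was -0.17 and -0.21; glycolysis was -0.43 and -0.47 there and -0.45 and -0.47 in the difference; ribosomal proteins in the difference were -0.0655 and -0.0863. With zeros set to 3 reads, all 128 list medians stayed inside the interval of the median over members. That setting could move few values far, since 3 reads in a gene of 2 kb correspond to 0.103 FPKM or less beside a pseudocount of 1. It says little about zeros that are failed estimates. The island comparison by genome sequence was not run, nor were its alternatives of pseudocount, filter, scaling, island definition and distance in that form.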

Other observations

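Tests of gene reads against denominators, and both added gene lists, were chosen only after the result was seen; exonic islands were an alternative chosen after seeing the data. Weighing the longer islands beside the shorter ones, and matching on GC content, were decided after the first island percentiles were seen.

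Interferon-induced genes stood higher in DKO_NP than in WT_NP. Ifi27l1 and Isg15, a ubiquitin-like protein, stood at 21.9 and 24.9 FPKM in DKO_NP against 0.212 and 1.27 in WT_NP; both were noticed first and left out of the list that was then made. Of the 18 listed genes at or above 1 FPKM, 12 were at least 2-fold higher and none lower after scaling (median log2 ratio 1.12), and the median as deposited lay at percentile 100 among matched random lists. Rtp4 was 21.1-fold higher (13.5 to 36.8), Oasl2 10.5-fold (7.89 to 14.1) and Ifit1 13.6-fold (9.02 to 21.7). More than a few single genes may thus be involved; a response to RNA of reactivated repeats was not tested, since repeats were not analysed here. In DKO_ES over WT_ES the list's median was 0.28, at percentile 99.2, with none of 13 at 2-fold as deposited and 1 after scaling.

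Erythroid genes other than globins stood lower in DKO_NP, as the embryonic globins did. The median of 10 such genes was -0.83 as deposited and -1.19 after scaling, with 7 at least 2-fold lower, and the deposited median lay at percentile 0.22 of the random lists. Alas2, the first enzyme of haem synthesis in red cells, was 8.02-fold lower (6.16 to 10.7). This is consistent with more erythroid cells in the WT_NP culture; with 1 culture it remains a hypothesis.

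X-linked genes were 53 of the 310 genes at least 2-fold higher in DKO_ES than in WT_ES after scaling, 17.1%, while 3.83% of the 12269 genes with a chromosome were X-linked and 11.9 would be there by chance. A larger dose of the X chromosome is argued against: among genes at or above 5 FPKM the median X-linked gene lay 0.14 above the autosomal one on the log2 scale. In DKO_NP over WT_NP, 65 of 588 higher genes were X-linked, against 22.7 by chance.

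Most genes had lower FPKM in WT_NP than in WT_ES. Reads in genes of 1 kb or more were estimated to be 1.23 times those of WT_ES, whereas the per-million denominator was 2.63 times as large. The gene reads were computed from FPKM and these same denominators. The contrast therefore restates the lower FPKM and cannot show what the denominator counts. In WT_NP the estimated gene reads, 29.2 M, were below the denominator of 38.1 M. That it counts reads outside the listed genes remains possible but was not separately shown. In WT_ES, DKO_ES and DKO_NP they were 23.8, 25.7 and 27.6 M, above denominators of 14.5, 15.8 and 26.3 M. A denominator that holds all gene reads cannot be smaller than they are. The gene reads are estimates, however, a median of 1.12 times those from the steps with a 90th percentile of 2.62. The excess can therefore lie in the estimates, and what the denominator counts stays open. The 20 most abundant genes held 36.0% of gene reads in WT_NP and 24.2% in WT_ES, which left the others 0.845 of their share. Whether this adds to the median shift of -0.82 cannot be told apart from the denominator. The choice of denominator was the authors', and no biological explanation was tested.

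Genes with an exonic CpG island over 2 kb from every transcript start had slightly lower medians in the knockout with the shorter islands. Their scaled median in DKO_ES over WT_ES was -0.05 over 4232 genes against 0.01 over all searched, and in DKO_NP over WT_NP -0.05 over 4307 against 0.02, each at percentile 0 of random lists matched on expression and length. GC content took part of this: the scaled median in DKO_ES over WT_ES went from 0.12 in the fifth part of genes lowest in GC content to -0.10 in the highest, a wider span than the island difference. Random lists matched on expression and GC content of the longest transcript, but not on gene length, had a central 95% of -0.03 to -0.01 there. The ES cell median still lay at percentile 0 of these lists. As the whole cause in ES cells, GC content of the whole transcript is thus argued against. The matching did not cover GC or CpG content within the exons, so a library bias at that scale is not excluded. The longer islands, of 500 bp or more, also had stricter cutoffs, with GC over 55% and a ratio of observed to expected CpG over 0.65. The shorter ones, of 200 bp or more, had cutoffs of 50% and 0.6. With the longer islands the ES cell median was -0.16 over 499 genes, again at percentile 0, but the NPC one lay at percentile 72.4. The ES cell median of all genes with an island thus lay outside the random range with each definition, while the NPC values depended on the definition. Length, both cutoffs and the genes searched changed together, so the part of each cannot be told apart. Of the shorter islands, 1552 genes without one near a start in an exon had an ES cell median of -0.02. It lay at percentile 2.52 of lists matched on expression and GC content, inside the central 95%, but at 0.01 of those matched on expression and length. With the longer islands 403 such genes had -0.14, at percentile 0 of both kinds of list. Whether lack of Dnmt3a and Dnmt3b lowers these genes stays open. In DKO_NP over DKO_ES the same genes differed more, where the median was 0.39 against 0.04 over all searched with the longer islands and 0.09 against 0.00 with the shorter ones, each at percentile 100. Of the latter, only the 2850 genes that also had an island near a start in an exon were higher, at 0.18. The other 1605 had -0.05, at percentile 0.13. With the longer islands, in contrast, the 438 without one near a start had 0.31, at percentile 100. In WT_NP over WT_ES the medians were 0.24 against 0.07 and 0.10 against 0.02, at percentiles 65.7 and 90.9 of lists matched on expression and length, but at 99.8 and 100 of lists matched on expression and GC content. Islands outside exons were not analysed here, and the differences are far under 2-fold.

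Rn45s, the ribosomal RNA precursor, was listed at 4222.5 FPKM in DKO_NP and at 0 in the other libraries.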
